A study of Mus musculus with 8 samples.

How the data were processed

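Visual cortex of wild-type C57Bl6 mice was profiled at postnatal day 24, 4 days after removal of 1 eye at postnatal day 20. Most fibres of the mouse optic nerve cross the midline, so the hemisphere opposite the removed eye is called deprived and the hemisphere on the same side non-deprived. Per the labels' protocols, 4 mice were operated on, visual cortex was dissected from coronal sections, and about 10 µg of total RNA was made into biotin-labelled cRNA for 1-colour short-oligonucleotide arrays. There were 8 arrays, 4 per group, numbered 1 to 4 in each group in the sample titles. The series design text speaks of pooled samples from 4 hemispheres of each kind, so it is unclear whether an array holds 1 animal or a pool. The per-gene p-values and those of the permutation tests therefore rest on the spread between these samples, which may be technical.

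The deposited values are linear signal intensity per probe set, made with MAS5 per the submitters' processing notes. MAS5 combines the perfect-match and mismatch probes of a probe set into 1 signal and scales each array to a common trimmed mean. The version and settings are not given in the sources used here. The table held 12488 probe sets. The mean of each array without the highest and lowest 2% of values was about 500, and 0 columns of sample values were left unused. The number of arrays limits the precision.

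Each array was rescaled to the same 2% trimmed mean, which changed the values by almost nothing. The 66 control probe sets were removed, and log2(signal + 15.3) was taken, the pseudocount being the 10th percentile of all signals. Differences on this scale understate the change of dim genes. Probe sets whose mean log2 value over all 8 arrays lay above the 40th percentile were kept, which left 7453 of 12422 and corresponds to a signal of about 110. Of all probe sets, 10833 were paired with 1 gene symbol in the platform annotation, 396 with several and 1193 with none, and genes were named only from the first kind. Symbols of 10817 of these were updated through Entrez identifiers to the gene table of the GRCm38.p6 assembly, which was used for names only.

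Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. All differences are deprived minus non-deprived. For gene lists, the probe set with the highest mean stood for each of 5675 genes. A list was tested with limma's camera at a preset correlation between genes of 0.01, with an estimated correlation and fry alongside. Camera sets the genes of a list against all other genes, so at this preset its p does not measure the spread between arrays. The adjustment ran over the 21 lists with 5 or more measured genes of 25 fixed lists. The immediate-early score was the mean log2 value over that list and was tested with an exact two-sided permutation test over 70 assignments, for which the smallest possible p is 0.0286. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

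The lists were immediate-early transcription factors, activity-regulated effectors, MAPK phosphatases and feedback regulators, MHC class I, GABAergic interneurons, GABA-A receptors, glutamate receptors, presynaptic release, extracellular matrix, the insulin-like growth factor axis, neurotrophins and neuropeptides, cortical layers, the circadian clock, heat shock and glucocorticoid response, oxidative phosphorylation and voltage-gated channels. Markers of oligodendrocytes, astrocytes, microglia, endothelium with mural and meningeal cells, blood, choroid plexus, hippocampus, striatum and thalamus completed them. The groups, tests, lists, alternative settings and rule for named genes were chosen before the data were examined. Adjustment of members over their list alone was not among those tests. By the rule for named genes the text names the largest changes past the threshold. Where fewer than 10 passed in a direction, it names the 10 probe sets with the smallest p, as values that did not pass. It also takes the members of each list with the smallest p, of which the text gives examples picked after their values were seen, and Fos, Egr1, Arc, Bdnf, Nr4a1, Junb, Homer1 and Nptx2 whatever their result. No probe set carried the name Arc in the annotation used, so Arc was not analysed here. Fosb, Egr2, Btg2, Jun, Sst, Npy, Rgs2, Pim3 and Tiparp were named after their values were seen.

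Whether the shared numbers pair the samples was checked from the data, since the labels give numbers but do not say that a number marks a mouse. Deviations from the group means correlated at 0.16 to 0.42 between samples of the same number, against -0.27 to 0.12 between samples of different numbers. All 4 pairs lay above the limit of 0.1 set for this check, so results with the number as a block are given where they change a call.

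The analysis was tested on simulated data made from these samples. Same-numbered samples were given a shared part at the correlation of 0.39 estimated from these data, so a gain from the block was built in. Probe sets varied independently of each other and each setting had 1 draw, so the values below are not rates for the real data. Without a block, limma recovered 35% of probe sets lowered by 0.7 on the log2 scale, 80% of those lowered by 1 and 100% of those lowered by 2, among 200 changed of 7453. When only the 20 immediate-early genes were lowered by 0.7, it recovered 0 over all probe sets and 16 when adjusted over the list alone. With the replicate block it recovered 5 of these 20 over all probe sets, with 3 false calls, and 17 when adjusted over the list alone. Among the 200 changed, the block recovered 65% of those lowered by 0.7, with 5 false calls against 0 without it. Alternatives covered scaling, pseudocount, the filter on dim probe sets, the replicate block, variance settings, the list test and leaving out each sample.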

Results

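Expression in visual cortex was compared between hemispheres of mice with 1 eye removed, with 4 arrays of non-deprived and 4 of deprived cortex. The median signal per array was 182 to 209, and log2 values of different arrays correlated at 0.926 to 0.973. The comparison asks which transcripts differ between the hemispheres 4 days after 1 has lost its main eye's input. No cortex of unoperated mice was among the samples, so a value called lower or fallen is so relative to the non-deprived hemisphere.

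Transcription factors that neurons induce within minutes of activity were lower in deprived cortex. Fos, whose protein is part of the AP-1 complex, had a signal of 2818 ± 665 in non-deprived and 1495 ± 165 in deprived cortex (SD, n = 4 each). Its log2 difference of signal plus pseudocount was -0.89, a fold of 0.541 on that scale. Nr4a1, an orphan nuclear receptor, went from 3100 ± 916 to 1711 ± 284, and the zinc-finger factor Egr1 from 6703 ± 1999 to 4018 ± 775. Junb, an AP-1 partner of Fos, went from 1465 ± 146 to 913 ± 145. These genes were lower in the deprived sample of 4 of 4 same-numbered pairs.

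As a group, 18 of the 20 measured genes of the immediate-early transcription factor list lay below 0, with a mean log2 difference of -0.36 and a median of -0.31. The name of this list is loose, as not all of its genes, such as Btg2 and Per1, encode DNA-binding factors. In limma's camera test the list fell with adjusted p = 9.36e-14, and with adjusted p = 0.0178 with an estimated correlation. With the replicate block these were 1.17e-12 and 0.127. Adjusted over the list alone, 8 members fell, against 0 adjusted over all probe sets: Fos, Junb, Nr4a1, Egr1, Ier2, Fosb, Egr2 and Btg2. Their adjusted p in limma over the list ran from 0.00394 for Fos to 0.0458 for Btg2. Jun did not pass, at a log2 difference of 0.32 ± 0.25 (SE), with 0.10 without non-deprived replicate 3 and 0.50 without non-deprived replicate 4. A dim probe set of Fos, left out by the filter, had 0.45, and a dim one of Egr1 had 0.16. Fosl1 and Maff, genes of the list that the filter left out as dim, had 0.37 and 0.29. With no filter the list's mean was -0.30. The mean score of the list was 9.64 ± 0.143 in non-deprived and 9.28 ± 0.0792 in deprived cortex (SD, n = 4), exact permutation p = 0.0286, the smallest possible. It was lower in 4 of 4 pairs, by -0.30 to -0.46, and the exact sign-flip p over pairs was 0.125, the smallest that 16 sign patterns allow.

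**Figure D1:**
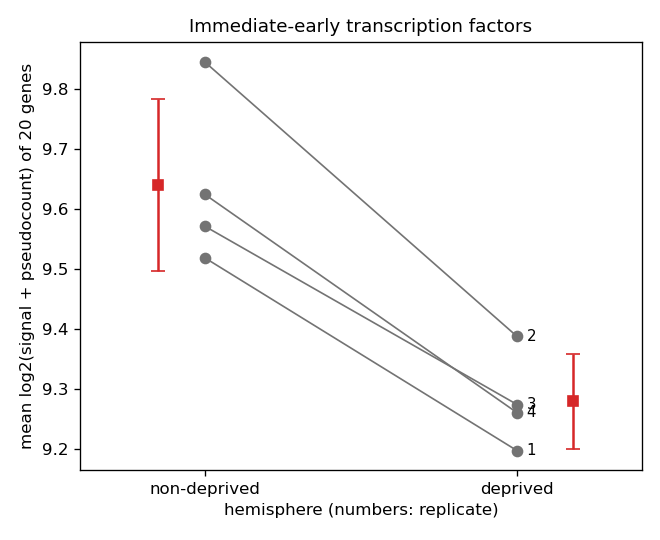
Mean log2(signal + pseudocount) of 20 genes of the immediate-early transcription factor list on each array, with grey lines joining samples of the same replicate number and red squares giving mean ± SD of 4 arrays. All 4 lines slope down from non-deprived to deprived cortex.

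Genes that act downstream of activity at synapses and in signalling were also lower as a group. Bdnf, a secreted neurotrophin, had a signal of 2016 ± 540 in non-deprived and 1112 ± 346 in deprived cortex (SD, n = 4), and Nptx2, a secreted pentraxin that clusters AMPA receptors, 845 ± 157 and 559 ± 123. Gadd45b had 326 ± 16.5 and 191 ± 75.1. Of 23 measured effectors, 16 lay below 0, and the list fell with a mean log2 difference of -0.24 (camera adjusted p = 1.17e-05, and adjusted p = 0.0178 with an estimated correlation, or 0.127 with the replicate block). The exact permutation p of that mean was 0.0286. No single member passed without the block, 0 adjusted over the list alone and 0 over all probe sets, Bdnf being nearest with a limma adjusted p of 0.0703 over the list. With the replicate number as a block, 7 passed adjusted over the list alone: Bdnf, Nptx2, Gadd45b, Rgs2, Tiparp, Pim3 and Scg2. That number was 2 to 5 when a pair was left out. Homer1, a postsynaptic scaffold gene, did not pass, at -0.19 ± 0.36 (SE), lower in 2 of 4 pairs. Its value was 0.06 without non-deprived replicate 1 and 0.15 without deprived replicate 4, and a dimmer probe set of it left out by the filter had -0.97.

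Of the MAPK phosphatases and feedback regulators, Dusp6 and Dusp1 fell. Both encode phosphatases that inactivate MAP kinases. Dusp6 had a signal of 2614 ± 250 in non-deprived and 1775 ± 203 in deprived cortex, and Dusp1 3162 ± 262 and 2250 ± 349 (SD, n = 4). They were 2 of 12 measured members adjusted over the list alone, against 0 over all probe sets, with limma adjusted p of 0.0148 and 0.0223. The number was 0 without non-deprived replicate 2, and 1 without non-deprived replicate 1 or deprived replicate 1, 3 or 4. The list's mean was -0.10 and its camera adjusted p = 0.0346, with adjusted p = 0.315 with an estimated correlation and 0.062 with the replicate block. The exact permutation p of the list mean was 0.2. The call was also lost without non-deprived replicate 1 (-0.07), without non-deprived replicate 2 (-0.08) and without deprived replicate 4 (-0.06), and with the Gapdh control ratio as a covariate (camera adjusted p = 0.122).

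**Figure D2:**
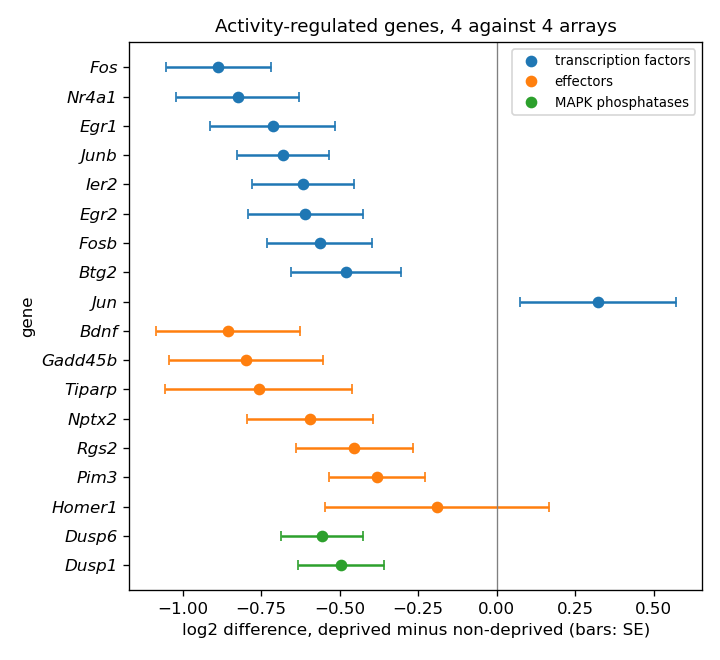
Log2 difference, deprived minus non-deprived, of named activity-regulated genes with SE bars, coloured by list. Fos lies at -0.89, Bdnf at -0.86 and Dusp6 at -0.56, while Jun lies at 0.32 with a wide SE bar.

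Neurotrophin and neuropeptide precursor genes were lower as a list. The list shares 4 measured genes with the effectors, Bdnf among them, and 6 with the interneuron list. Of 17 measured, 13 lay below 0, with a mean of -0.22 and a camera adjusted p = 3.74e-04. The call was lost with adjusted p = 0.113 with an estimated correlation, and the exact permutation p of the list mean was 0.0857. Tac1, the substance P precursor, had a signal of 214 ± 56 in non-deprived and 137 ± 49 in deprived cortex, and somatostatin (Sst) 4097 ± 1270 and 2956 ± 1209 (SD, n = 4). Adjusted over the list alone 0 members passed without the block, as over all probe sets, and 5 with it: Bdnf, Sst, Npy, Tac1 and Scg2. With the block as a random effect the number was 1, and it was 1 to 4 when a pair was left out. The 3' to 5' ratio of the actin control probe sets, a measure of RNA integrity, was 1.39 ± 0.179 in non-deprived and 1.64 ± 0.239 in deprived cortex (SD, n = 4, exact permutation p = 0.171). The Gapdh ratio went the other way, 0.898 ± 0.0543 and 0.842 ± 0.0345 (SD, n = 4, exact permutation p = 0.143). The list's mean was -0.14 with the actin ratio as a covariate, where the call was lost (camera adjusted p = 0.164), and -0.19 with the Gapdh ratio (0.0321), and with the actin ratio the difference of Sst turned to 0.03 and that of Npy was -0.01.

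Oxidative phosphorylation genes, which encode subunits of the mitochondrial respiratory chain and ATP synthase, were lower as a list. Of 34 measured, 30 lay below 0, with a median of -0.21 and a mean of -0.16. Atp5c1, an ATP synthase subunit, had a signal of 4810 ± 178 in non-deprived and 3966 ± 417 in deprived cortex (SD, n = 4). Ndufa1, a complex I subunit at a low signal, lay at 0.98 ± 0.28 (SE). The camera adjusted p was 2.17e-04, with adjusted p = 0.495 with an estimated correlation, and 0 members passed in either direction adjusted over the list alone, as over all probe sets. The mean (exact permutation p = 0.457) was lower in 2 of 4 pairs, -0.05 without deprived replicate 2, where the call was lost, and from there to -0.28 without deprived replicate 4, with -0.25 without non-deprived replicate 2, -0.10 without non-deprived replicate 3 or 4 and -0.09 without deprived replicate 3. Both arrays numbered 2 had the lowest scores of this list in their groups (10.9 in non-deprived and 10.7 in deprived cortex). Leaving out 1 of them therefore also shifts the mean by what the pair shares. The list's mean was 0.11 with the actin ratio as a covariate and -0.13 with the Gapdh ratio, and the call was lost with either (camera adjusted p = 0.0679 and 0.0596).

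**Figure D3:**
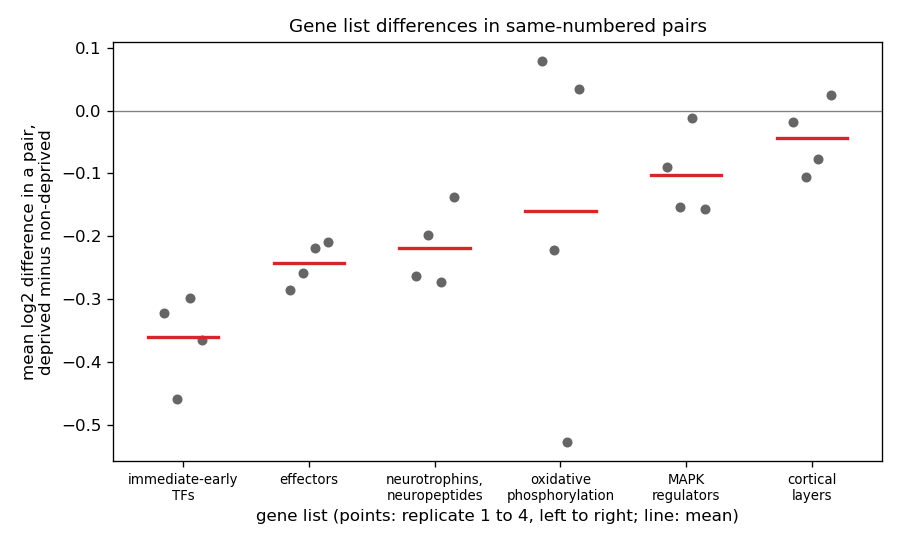
Mean log2 difference of 6 gene lists in each same-numbered pair, deprived minus non-deprived, with a red line at the mean of 4 pairs. The immediate-early and effector lists lie below 0 in each pair, and oxidative phosphorylation runs from -0.53 to 0.08.

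No other tested list passed at the preset correlation. Interneuron genes had a mean of -0.12 (camera adjusted p = 0.133), with Cort, the cortistatin precursor, at 536 ± 80.7 and 382 ± 174 (SD, n = 4), and with the block fry gave an adjusted p of 0.0161 (without it, 0.328). Presynaptic release genes had -0.11 and heat shock and glucocorticoid genes -0.10 (camera adjusted p = 0.133 for each). Interneuron and presynaptic genes were lower in 4 of 4 pairs, and heat shock and glucocorticoid genes in 3 of 4. The exact permutation p of the list mean was 0.0571 for interneuron and for presynaptic genes, and 0.114 for heat shock and glucocorticoid genes. Of the called lists, it was 0.0857 for neurotrophins and neuropeptides, 0.2 for MAPK regulators and 0.457 for oxidative phosphorylation. A call by camera thus does not mean a clearer difference between arrays. Thalamus markers had a mean of 0.14 (0.175), higher in 4 of 4 pairs, with 0.09 without deprived replicate 2 and 0.07 with the actin or the Gapdh ratio as a covariate. Clock genes had 0.10 (0.234), with Arntl at 0.39, Per3 at 0.50 and Per1 at -0.28, and 5 of 16 measured below 0. Their mean was 0.04 without non-deprived replicate 4, 0.06 without deprived replicate 1, 0.15 without deprived replicate 4 and 0.01 with the actin ratio. The camera adjusted p was 0.361 for glutamate receptors, 0.41 for the insulin-like growth factor axis, 0.462 for cortical layers, 0.49 for extracellular matrix, 0.557 for GABA-A receptors and 0.594 for MHC class I. It was 0.669 for oligodendrocyte markers and 0.841 for astrocytes, microglia, endothelium and voltage-gated channels. Means were -0.04 for cortical layers, -0.02 for oligodendrocytes, 0.07 for astrocytes (higher in 4 of 4 pairs, but -0.01 without deprived replicate 2), 0.02 for microglia and 0.02 for endothelium. Of lists too short to test, blood had a mean of -0.10, choroid plexus 0.11, hippocampus -0.05 and striatum -0.07. With the block and adjusted over the list alone, Igf2 was higher in its list (adjusted p = 0.048 in limma) and Cdkn1a lower in the heat shock list (0.0421), and neither passed over all probe sets. With the block fry also passed the insulin-like growth factor list (adjusted p = 0.0499, without it 0.722) and the neurotrophin and neuropeptide list (0.0161, without it 0.165). Fry passed the immediate-early list (adjusted p = 0.0161 with the block, 0.0208 without it) and the effectors (0.00804 and 0.0166) in both fits.

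Across all 7453 probe sets, limma called 0 lower and 0 higher, with a smallest adjusted p of 0.995. At an unadjusted p under 0.05 there were 199 probe sets, 91 lower and 108 higher, where chance gives 372.6. That number was 429 without deprived replicate 4, above the chance value, 311 without deprived replicate 1, 133 without non-deprived replicate 4 and 368 with array weights. The fit with the replicate block also called 0 and 0, with 524 at an unadjusted p under 0.05 and a smallest adjusted p of 0.116, shared by probe sets of Tmem129, Bdnf, Fos, Junb and Nr4a1. The random block called 0 and 0, with 535. Values of the 4 deprived arrays lay entirely below the others for 60 probe sets and entirely above for 91. For both directions together, chance gives 2.86% of probe sets, or 213. Among probe sets with the smallest p that did not pass, Myt1l, a neuronal zinc-finger factor, had 966 ± 122 in non-deprived and 1546 ± 285 in deprived cortex, and Bcl2l11, a pro-apoptotic BH3 gene, 169 ± 48.3 and 302 ± 77.1 (SD, n = 4). Nbl1, a secreted BMP antagonist, had 440.0 ± 61.6 and 166 ± 107. The others higher were Plac1 (log2 difference 0.70), Abcb4 (0.78), Aak1 (1.42), Ndufa1 (0.98), Epb41l4a (0.99), Rgs19 (0.70), Neo1 (0.48) and Matn2 (0.58), and the others lower outside the lists above were Rnh1 (-1.34) and Ebi3 (-1.03). In non-deprived cortex Abcb4, Aak1, Ndufa1 and Epb41l4a were dim, with mean signals of 99.8, 99.85, 79.35 and 88, below the filter signal of about 110. Rnh1 and Ebi3 were dim in deprived cortex, at 74.4 and 77.25. The 10th percentile of signal was 13.4 ± 0.678 in non-deprived and 17.2 ± 2.70 in deprived arrays (SD, n = 4, exact permutation p = 0.0286). It was higher in 4 of 4 pairs, with an exact sign-flip p over pairs of 0.125, the smallest possible.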

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

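The dilution test, the actin-ratio test of oxidative phosphorylation genes and the results with the Gapdh ratio were made only after the result was seen. A sample stood far from the other 3 of its group in 9 of the 170 groups examined, and chance flags about 1 in 20 groups (8.5 here). As a share of the group's range, the gap was 0.858 for Junb, 0.855 for Btg2, 0.847 for Homer1, 0.857 for Cort and 0.951 for Igfbp2, each set by deprived replicate 4. Dusp1 had 0.927, set by deprived replicate 2, and Wfs1 0.952, set by deprived replicate 3. Epb41l4a had 0.952 and the heat shock and glucocorticoid score 0.851, both set by non-deprived replicate 1.

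The lower values of activity-regulated genes were weighed against technical explanations. The 10th percentile of signal was 13.4 ± 0.678 in non-deprived and 17.2 ± 2.70 in deprived arrays (SD, n = 4). Its exact permutation p of 0.0286 equals that of the immediate-early score, and the cause of this array difference was not tested. Quantile scaling, which gives all arrays the same distribution of signals, left the immediate-early list mean at -0.38. After cyclic loess scaling the immediate-early list mean was -0.38, and none of 10000 random lists matched on signal level was as low (lowest -0.17), which argues against scaling. For oxidative phosphorylation genes (-0.16) none was as low either (lowest -0.14). Random lists hold unrelated genes, so they cannot tell a group difference from variation that a list's genes share between arrays. With the actin 3' to 5' ratio as a covariate the immediate-early list mean was -0.38, and -0.52 to -0.30 with each sample left out. With the Gapdh ratio it was -0.29. Both argue against RNA degradation as the whole cause. The cortical layer list had a mean of -0.0443, which argues against dilution by other tissue as the whole cause. Thalamus markers were nevertheless higher in the deprived sample of 4 of 4 pairs (mean 0.14, or 0.09 without deprived replicate 2). Astrocyte markers were too (mean 0.07, or -0.01 without deprived replicate 2). Both arrays numbered 2 had the highest astrocyte scores of their groups (10.6 and 10.7). Leaving out 1 of them therefore also shifts the mean by what the pair shares. Some difference in tissue or cell types stays open. Loss of input from the removed eye may account for the lower values, as a hypothesis that was not tested. Both groups came from mice with 1 eye removed, so a fall in deprived cortex cannot be told apart from a rise in non-deprived cortex. Handling that differed between hemispheres was not tested.

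The lower oxidative phosphorylation genes gave another outcome. Scaling is argued against by a median of -0.18 after cyclic loess. With the actin ratio as a covariate the mean became 0.11, and 0.02 to 0.28 with each sample left out, but with the Gapdh ratio, which went the other way (0.898 ± 0.0543 in non-deprived and 0.842 ± 0.0345 in deprived arrays), it was -0.13, and -0.37 to 0.0154 with each sample left out. RNA integrity therefore stays open, as these ratios disagree. Of 35 splits of the samples, 16 gave a list difference as large, the highest 0.43 against 0.16 for the real split, so variation between arrays shared by these genes may account for it. A biological difference was not excluded.

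Without the block, 199 probe sets had an unadjusted p under 0.05, where chance gives 372.6. The number was 429 without deprived replicate 4, 311 without deprived replicate 1, 282 without non-deprived replicate 2 and 133 without non-deprived replicate 4. With array weights it was 368. The size of this shortfall therefore depends on which arrays were used, and it was gone without deprived replicate 4. Leaving out 1 array of a pair also adds what the pair shares to the group difference. The change therefore need not come from the omitted array alone, and whole pairs were not left out for this number. The 8 splits that part all 4 pairs had a median of 132.5 probe sets at that p, and the 3 splits that keep pairs whole 935, with up to 1247. That is consistent with same-numbered samples sharing variation, which the fit without the block counts as spread, though these splits were not repeated without deprived replicate 4; whether a shared animal or a shared processing day is the source was not tested. The real split had 199, above the 151 of the other splits that part all pairs.

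Other splits also bear on the counts. For called probe sets, 35 of 35 splits gave as many as the real 0, with 1 in the highest other; no split can give fewer than 0, so this count says nothing about chance. For called lists, 1 of 35 gave as many, the real split with 5 against 4 for the highest other, and for immediate-early members adjusted over the list alone 1 of 35 did, with 8 against 1. Among splits that part all pairs the highest others were 4 lists and 0 members. Other splits gave up to 0.25 for the neurotrophin and neuropeptide list, against 0.22 for the real split (exact permutation p = 0.0857). Chance is thus not excluded for it, nor for the MAPK (exact permutation p = 0.2) and oxidative phosphorylation lists (0.457). For the immediate-early and effector lists the exact permutation p of 0.0286 is the smallest possible, ignores the pairs and is not adjusted over lists. With pairs kept, the exact sign-flip p of the immediate-early score was 0.125, also the smallest possible, so that test cannot exclude chance.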

How the results depend on the processing

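Covariate results, the alternatives for members counted over a list alone and blocked counts without a pair were chosen after seeing the data; the cause of the changes below was not tested. Probe set calls were 0 and 0 under all 22 alternatives. The immediate-early score kept its direction under 20 alternatives, from -0.45 to -0.29, and from -0.40 to -0.29 with each sample left out; with the replicate block it stayed at -0.36 with an exact sign-flip p of 0.125, as few pairs allow no smaller. Immediate-early members numbered 6 to 9, and MAPK members 0 to 2 with a sample left out and 1 with the actin ratio. Called lists went from 5 to 2 with an estimated correlation, 2 with fry and 4 to 6 with a sample left out. Effector members went from 0 to 7 with the replicate block, 9 with the random replicate block, 2 with array weights and 0 to 3 with a sample left out. Neuropeptide members went from 0 to 5 with the replicate block, 1 with the random replicate block, 1 with no filter, 1 with the filter at the 60th percentile and 0 to 4 with a sample left out, 4 being without deprived replicate 4. The replicate block ended the MAPK list's call and changed no other camera call at the preset correlation. With the actin ratio the oxidative phosphorylation mean turned to 0.106 and the neuropeptide list lost its call (-0.136); with the Gapdh ratio the oxidative phosphorylation (-0.127) and MAPK (-0.0886) lists lost theirs. Sst, which passed over its list with the replicate block, turned to 0.029 with the actin ratio. The other directions that turned were of lists or genes without a call in the main fit. Endothelium had -0.0195 with quantile and -0.0248 with cyclic loess scaling, and microglia -0.00116 with cyclic loess and -0.0237 with the filter at the 60th percentile. With no filter, the insulin-like growth factor axis had 0.000507, channels 0.0216, oligodendrocytes 0.029, microglia -0.0151, blood 0.0896 and hippocampus 0.147. With the actin ratio Igfbp2 had 0.0173, MHC class I 0.0114, GABA-A receptors -0.0138, glutamate receptors 0.0368 and blood 0.0486. With the Gapdh ratio GABA-A receptors had -0.0289, oligodendrocytes 0.0300, microglia -0.0174, endothelium -0.0398 and choroid plexus -0.219. Leaving out each sample gave ranges of -0.0762 to 0.016 for oligodendrocytes, -0.0097 to 0.0679 for microglia, -0.0265 to 0.085 for endothelium, -0.152 to 0.104 for hippocampus, -0.154 to 0.0837 for striatum, -0.0205 to 0.25 for choroid plexus, -0.151 to 0.000405 for MHC class I, -0.00948 to 0.137 for astrocytes, -0.0179 to 0.158 for extracellular matrix, -0.277 to 0.00388 for blood, -0.0571 to 0.0517 for channels and -0.339 to 0.153 for Homer1. Presynaptic genes passed camera with the pseudocount at the 25th percentile (-0.146) and with no filter (-0.213), and heat shock genes with no filter (-0.109); without non-deprived replicate 1 heat shock (-0.139) and glutamate receptor genes (-0.0895) passed. Dim probe sets limit what these arrays can show, since the signal at the filter was about 110.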

Other observations

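The tests here were chosen only after the result was seen. Families of genes outside the fixed lists were formed from gene symbols, and since no definition of a family had been written down, results of both definitions tried are given. By the first 3 characters of the symbol, which was run first, 4 of 43 families passed camera at the preset correlation, and by the letters before the first digit 3 of 44 did. By characters these were 56 Mrp genes (mean log2 difference -0.16), 39 proteasome genes named Psm (-0.12), 18 Ndu genes of complex I (-0.21) and 16 collagen genes (0.21). By letters, mitochondrial ribosomal protein genes were lower, with a mean log2 difference of -0.15 over 36 Mrpl genes and -0.19 over 20 Mrps genes, and collagen genes higher, with 0.25 over 14. With the replicate block 7 passed by characters, the same and Ank (adjusted p in camera 0.0274), Tim (0.0384) and Rps (0.0384), and 6 by letters, the same and Rpl (0.0334), Timm (0.0448) and Rps (0.0448). None held with an estimated correlation: 0 families passed both tests under either definition, with or without the block, with a smallest adjusted p of 0.654 with an estimated correlation by letters and 0.763 by characters, or 0.785 and 0.731 with the block. The hypothesis that such families differ between the hemispheres therefore had no backing from both tests together, but was not excluded. With the block no fixed list passed camera with an estimated correlation either (smallest adjusted p = 0.127), so that blocked result cannot decide it. The neurotrophin and neuropeptide list without the 4 genes it shares with the effectors had a mean of -0.20 over 13 genes, with a camera adjusted p of 0.0117 and an adjusted p = 0.305 with an estimated correlation.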
